A study of Mus musculus with 12 samples.

How the data were processed

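RNA from normal colon of ApcMin mice, which carry a truncating mutation in the tumour suppressor gene Apc and develop intestinal polyps, was profiled on Illumina bead arrays after 11 weeks on a diet deficient or sufficient in methyl donors. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on RNeasy columns with DNase I, and amplified to biotinylated cRNA with the MessageAmp kit. The labels name 2 animals on the sufficient diet and 4 on the deficient diet, with 2 samples from each, so the series holds 12 arrays.

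The scanner table gives for each array a mean bead intensity per probe, on a linear scale and not normalized as far as the values show, as deposited by the authors. Its second column per array is a detection p-value, per the file headers. The series matrix holds the authors' processed values on a log2 scale, with a median of 0 over the 12 arrays for each of the probes to within 1.47e-06. Set against the log2 scanner signal centred in the same way, over the 9314 probes with detection p under 0.01 on all 12 arrays, each matrix column correlated most with its own array, at 0.957 to 0.979, and at no more than 0.737 with any other. The matrix column medians were 0.0035, 0.15, 0.0031 and -0.12 for samples 1 and 2 of sufficient animals 1 and 3, -0.0031, -0.10, 0.03 and 0.01 for deficient animals 1 and 2, and -0.15, 0.13, -0.15 and -0.14 for deficient animals 3 and 4. The slopes ran from 1.11 to 1.19, so direction and scale followed the log2 signal. How the matrix was normalized before centring, and why its slopes exceed 1, stays unknown. It served as an alternative to the scanner signals.

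Signals were background-corrected and quantile-normalized with neqc in limma 3.58.1 (R 4.3.3), with negative controls inferred from the detection p-values and an offset of 16, and taken to log2. Probes with a detection p under 0.05 on at least 4 of the 12 arrays were kept, which left 13497 of 25697 (52.5%). Median signals before normalization ran from 59.4 to 71.5 and the number of probes with detection p under 0.05 from 12609 to 13241 per array. The number of animals, 2 and 4, limits the precision of every comparison. Over the kept probes any pair of arrays correlated at 0.952 to 0.993, and no arrays held identical values.

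Probes were named through the platform annotation, with symbols looked up by Entrez ID in a RefSeq table of the mouse assembly GRCm38.p6. Of the 25697 probes, 23978 had 1 symbol, 0 had several and 1719 are unnamed here; 23962 of the named probes were found in the RefSeq table and no symbol changed. For a gene with several probes, the probe with the smallest p is printed among the largest changes, and the probe with the highest mean signal in gene lists and for genes named in any case. For every named gene, all its kept probes moved in the same direction.

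The design was fixed before the data were examined. The 2 arrays of each labelled animal were averaged on the log2 scale and the 6 means were fitted with limma's lmFit and eBayes (deficient minus sufficient, two-sided, Benjamini-Hochberg over all kept probes, threshold 0.05). The residual degrees of freedom were 4 and the prior added 4.00. An exact permutation test has 15 splits of 6 animals into 2 and 4 and cannot go below p = 0.0667. The share of probes whose animals do not overlap between the diets is therefore given as a description. Gene lists (47, of pathways and of cell types) were tested with camera on the same means, with 1 probe per gene, the preset inter-gene correlation of 0.01 and adjustment over the 43 lists with at least 5 measured genes; camera with an estimated correlation and fry were run beside it. fry's p tests whether a list's genes move on balance in a given direction, without comparing them with other genes. For fits with a random block, a replicate block or a variance trend, camera was run on the fit's moderated statistics.

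The genes named include, per direction, the 12 with the largest log2 difference among probes past the threshold whose labelled animals do not overlap. Unnamed probes and provisional symbols were left out of these. The 3 members with the smallest p of each list past the threshold were also selected. Which of these 3 are given in the text follows no fixed rule, but later counts of named genes include all of them. Apc, Dnmt1, Dnmt3b, Ahcy, Lgr5, Axin2, Myc and Cdkn1a were named in any case. Dnmt3a was not detected on enough arrays, and Mtr, Mat2a and Mki67 were not analysed here.

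Sex-linked genes showed that the arrays of 4 labelled animals are not of the same sex. A second fit, chosen after seeing the data, therefore kept the diet labels and joined the arrays of these 4 animals by sex within their diet. These 6 units are called sex-matched pairs: labelled deficient animals 1 and 2 as they stand, the sufficient male pair (animal 1 sample 1 with animal 3 sample 2), the sufficient female pair (animal 1 sample 2 with animal 3 sample 1), the rejoined deficient male pair (animal 3 sample 1 with animal 4 sample 2) and the deficient female pair (animal 3 sample 2 with animal 4 sample 1). The diet means and the log2 differences are the same in both fits and only their errors differ. A list score is the mean over the genes of a list of the log2 signal minus its mean over the arrays or pairs.

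The fit was tested on simulated data: known changes were put into a set of the 13497 probes in 6 simulated animals with the spread of the sex-matched pairs. It recovered 6% of probes changed by 0.5 on the log2 scale, 82% of those changed by 1 and 100% of those changed by 2 or by 3, and called 9 unchanged probes. All sizes were planted together, and calls of the large changes loosen the Benjamini-Hochberg cutoff for the small ones. Recovery in the measured data may therefore be lower. In 20 simulated sets with no diet effect, a median of 0 and at most 2 probes were called with arrays averaged as labelled, and at most 0 with sex-matched pairs; the median share of probes with unadjusted p under 0.05 was 7.89% and 3.16%, and that of probes with no overlap between the diets 18.2% and 10.5%. The simulated probes were independent of each other, unlike measured genes.

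Alternatives covered background correction, normalization, the authors' values, the filter, the replicate unit, array weights, the variance model, the threshold and leaving out each animal. A fit with slide as a block was not run, since no slide is named in the files. A bound is given where no array of a diet had a detection p under 0.05: the brighter diet's mean against the mean, over the dim arrays, of the higher of the probe's own signal and the lowest signal of any detected probe, on normalized log2 values.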

Results

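The data are 12 arrays of normal colon from ApcMin mice, 4 from the diet sufficient in methyl donors and 8 from the deficient diet, labelled as 2 and 4 animals with 2 samples each. Methyl donors such as folate, methionine and choline feed the synthesis of S-adenosylmethionine, the donor for methylation of DNA and histones. The series asks what their depletion does to gene expression in normal colon. Values are normalised log2 signals, and a difference is deficient minus sufficient.

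The sexes of the arrays did not follow the animal labels. Eif2s3y and Kdm5d, genes of the Y chromosome, had log2 signals of 9.39 to 10.22 and 6.96 to 7.82 on 8 arrays, and of 4.47 to 4.56 and 4.53 to 4.61 on the other 4. Xist, the RNA that silences an X chromosome in females, lay at 4.85 to 5.06 on those 8 arrays and at 6.61 to 7.06 on the other 4. In both labelled sufficient animals and in labelled deficient animals 3 and 4, the 2 samples were of opposite sex by these genes. Labelled deficient animals 1 and 2 were male on both arrays. The diet groups held 2 male and 2 female sufficient arrays, and 6 male and 2 female deficient arrays. Animals are called labelled animals below for this reason, and the counts are given both with the labelled pairs and with arrays joined by sex within a diet (sex-matched pairs). A value of a gene given as ± SE is with labelled animals. Such an SE does not measure the spread between mice, since 4 labelled animals mix the sexes. With sex-matched pairs most of these SEs were larger, such as 0.34 against 0.10 for Clca4b. No gene given this way passed with sex-matched pairs, where the adjusted p of those past the threshold with labelled animals ran from 0.0540 to 0.469. The array deviations from the mean of all arrays, over 12320 autosomal probes, correlated at 0.37 to 0.73 within the 6 sex-matched pairs. Within the labelled animals they correlated at 0.03, 0.07, -0.25 and -0.27 for sufficient 1, sufficient 3, deficient 3 and deficient 4. The consensus correlation of samples of an animal was -0.23 as labelled and 0.33 with sex-matched pairs. The median SD between samples of an animal was 0.154 as labelled, and the median SD between animal means was 0.122. With sex-matched pairs the same SDs were 0.120 and 0.165. The first SD is of single arrays and the second of means of 2 arrays, so their sizes are not directly comparable within a pairing.

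**Figure D1:**
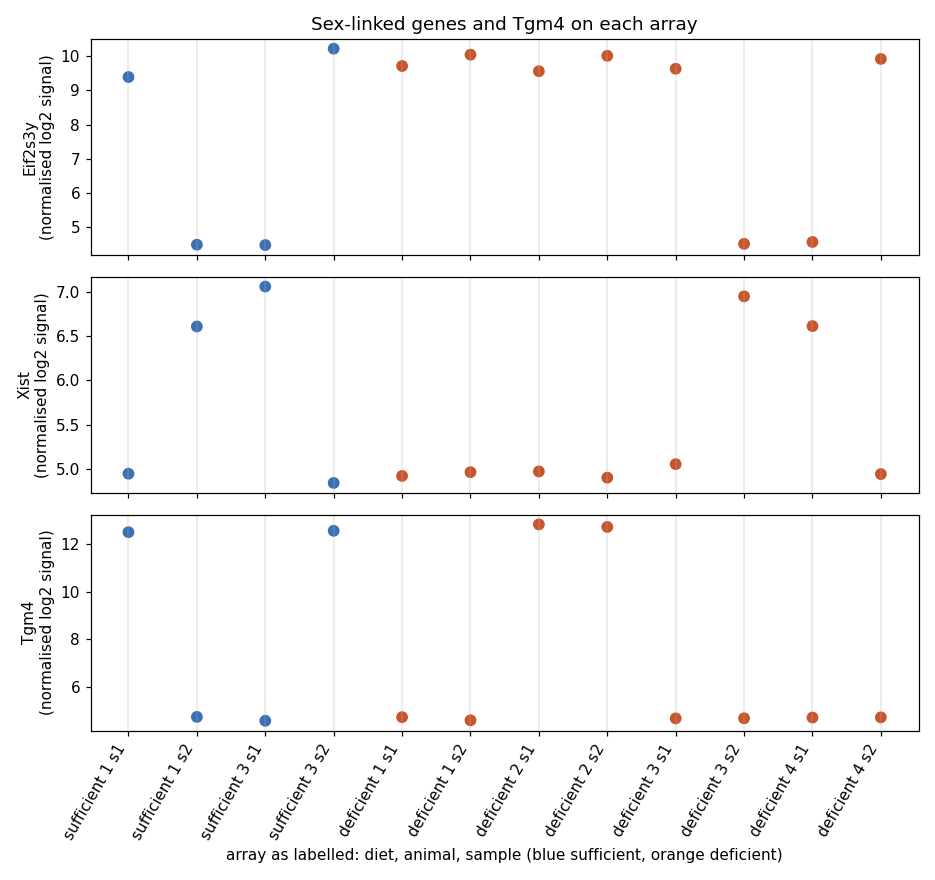
Normalised log2 signal of Eif2s3y, Xist and Tgm4 on each of the 12 arrays, named on the horizontal axis by labelled diet, animal and sample (blue sufficient, orange deficient; points are arrays). Samples 1 and 2 of sufficient 1, sufficient 3, deficient 3 and deficient 4 lie on opposite sides for Eif2s3y and Xist, and Tgm4 lies above 12.5 on 4 arrays.

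Of the 38 probes that passed with both pairings, 27 were lower and 11 higher in the deficient colon. Cxcl1, a chemokine that attracts neutrophils, fell by 3.77 on the log2 scale, from 9.26 ± 0.02 (SD, n = 2 labelled animals) to 5.49 ± 0.13 (SD, n = 4). Its SE was 0.10 (adjusted p = 4.24e-06) with labelled animals and 0.41 (adjusted p = 0.0250) with sex-matched pairs. Both labelled sufficient animals, and some deficient ones, average a male and a female array. The SDs in this paragraph therefore do not measure the spread between mice. Without the sufficient male pair Cxcl1 stood at -4.62, and without the sufficient female pair at -2.92. Mzb1, a chaperone of antibody assembly in plasma cells, fell by 3.24 (SE 0.34 and 0.39, adjusted p = 0.00205 and 0.0314). C1qtnf3, a secreted protein related to complement C1q, rose by 2.72 (SE 0.18 and 0.25, adjusted p = 0.000450 and 0.0204), from 6.16 ± 0.01 (SD, n = 2) to 8.88 ± 0.31 (SD, n = 4). Mfap4, a protein of elastic microfibrils, rose by 2.11 (SE 0.15 and 0.21, adjusted p = 0.000594 and 0.0226), and Tppp, which promotes tubulin polymerization, by 2.07 (SE 0.11 and 0.16, adjusted p = 0.000244 and 0.0132).

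With labelled animals, 1460 of 13497 probes passed the threshold, 716 higher and 744 lower, for 1204 genes; 46 were at least 2-fold higher and 100 at least 2-fold lower. With sex-matched pairs 38 probes passed, 11 higher and 27 lower, for 31 genes and 1 unnamed probe. All 38 were among the 1460. Both fits share the same log2 differences, so the direction of a probe could not differ between them. The labelled count fell to 98 without labelled sufficient animal 1 and to 87 without labelled sufficient animal 3. The sex-matched count was 0 without the sufficient female pair and 0 without the deficient female pair by limma, with 1141 and 1704 probes at unadjusted p under 0.05, and it was 6, 14 and 351 without deficient 1, deficient 2 and the rejoined deficient male pair. The diets differed in the share of males, and with sex as a covariate 7 of the 38 probes passed, 1 higher and 6 lower, with 1895 at unadjusted p under 0.05. These were 2 probes of Ckmt2 and 1 each of Tppp, Krt23, Irf4, Prg2 and Ceacam10 (adjusted p = 0.0413). The probes given above for Cxcl1, Mzb1, C1qtnf3 and Mfap4 did not pass (adjusted p = 0.0524), with differences of -3.63, -3.39, 2.68 and 2.07 in that fit. The adjusted p of the 38 reached 0.124 with sex as a covariate, and all kept their direction. Tgm4, a transglutaminase of the prostate, had log2 signals of 12.51 to 12.83 on the arrays of the sufficient male pair and of deficient 2, and of 4.57 to 4.73 on the other 8; without these pairs 1 sufficient and 3 deficient pairs were left, too few for a count to bear on these transcripts (0 probes by limma, 1712 at unadjusted p under 0.05). The differences of the 38 probes were then 0.791 to 1.24 times those with all pairs, in the same direction. The 38 were picked on all these pairs, so neither these ratios nor their direction with sex as a covariate is independent support.

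In 5748 probes (42.6%) the labelled animals of the diets did not overlap, 2952 higher and 2796 lower. Chance gives 13.3% for independent animals, and simulated sets with no diet effect gave a median of 18.2% with these labels. Over sex-matched pairs the number was 3379 (25.0%), 1692 higher and 1687 lower, against 10.5% in the simulated sets. Over the arrays, 854 probes (6.33%) had all 8 deficient arrays on the same side of all 4 sufficient arrays, 441 higher and 413 lower, where chance gives 0.404% for independent arrays.

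Among the 12 largest increases, 3 passed with both pairings (C1qtnf3, Mfap4 and Tppp). The other 9 passed with labelled animals only, and their adjusted p with sex-matched pairs ran from 0.0583 to 0.182. They included Ccn5, a matricellular protein, at 2.73 ± 0.43 (SE), Eln, the elastin gene, at 2.46 ± 0.32, Mettl7a2, a methyltransferase-like protein, at 2.27 ± 0.39, and Pi16, a marker of adventitial fibroblasts, at 2.22 ± 0.16. Mfap5, another microfibril protein, stood at 1.82 ± 0.16, Pdzk1, a scaffold of epithelial transporters, at 1.47 ± 0.23, Odf3b at 1.46 ± 0.10, Il17d at 1.45 ± 0.15 and Anpep, an aminopeptidase of the enterocyte brush border, at 1.44 ± 0.18. With sex-matched pairs the SEs of these 9, in the order given, were 0.47, 0.53, 0.42, 0.61, 0.37, 0.37, 0.26, 0.21 and 0.31. On the sufficient arrays, Ccn5 and Pi16 were detected on 2 of 4. Without the sufficient male pair Pi16 stood at 3.39, Pdzk1 at 0.91 and Anpep at 0.91, and without the sufficient female pair Pi16 stood at 1.05.

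Among the 12 largest decreases, 6 passed with both pairings: Cxcl1, Mzb1, Cd177, Pou2af1, Egr1 and Socs3. Cd177, a neutrophil surface protein, fell by 2.64 (SE 0.26 and 0.37), Pou2af1, a coactivator of B cell transcription, by 2.26 (SE 0.21 and 0.26), Egr1, an early growth response factor, by 2.22 (SE 0.27 and 0.31), and Socs3, an inhibitor of cytokine signalling, fell by 2.15 (SE 0.12 and 0.25). The other 6 passed with labelled animals only: Retnlb, an antibacterial goblet cell protein, at -2.48 ± 0.53 (SE), Ly6m at -2.41 ± 0.42, Clca4b at -2.30 ± 0.10, Il1b, a cytokine of inflammation, at -2.27 ± 0.21, Fosb at -2.15 ± 0.46 and Nox1, the colonic NADPH oxidase, at -2.13 ± 0.47. Their adjusted p with sex-matched pairs ran from 0.0645 to 0.270, with SEs, in the order given, of 0.90, 0.54, 0.34, 0.44, 0.53 and 0.64. On deficient arrays Retnlb was detected on 3 of 8 and Nox1 on 7 of 8; Retnlb lay at 8.38 and 8.40 on the arrays of the rejoined deficient male pair, within the sufficient range. Without the sufficient female pair Il1b stood at -1.48. All arrays of the diets were separate in 22 of these 24 genes, the exceptions being Pi16 and Retnlb. Over all kept probes the share was 6.33%. The 24 were picked for large differences and for labelled animals that do not overlap, so their separation is not independent support.

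**Figure D2:**
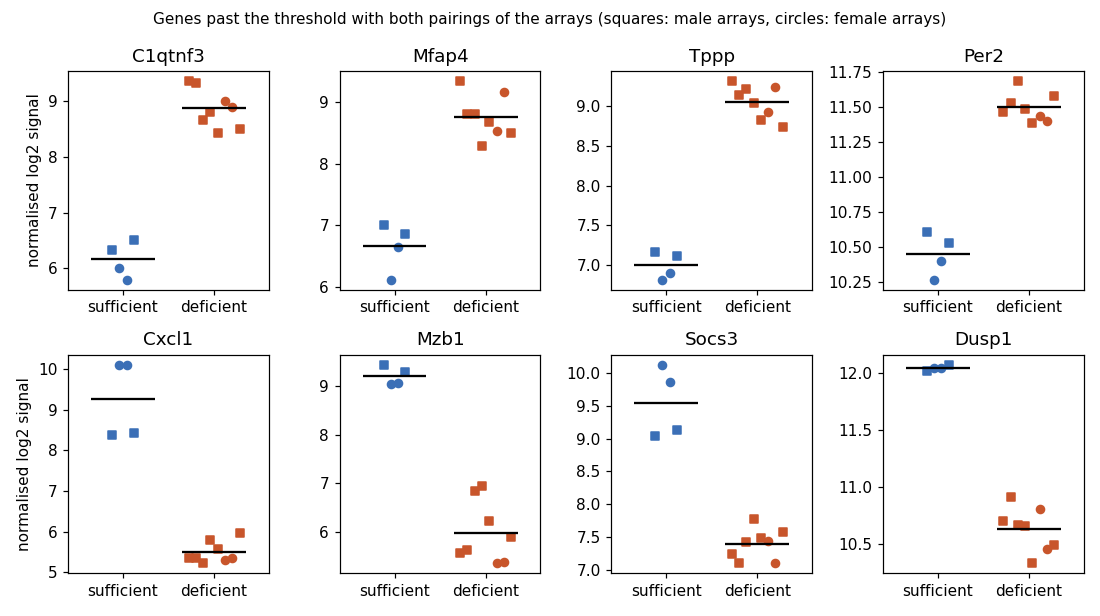
Normalised log2 signal on the vertical axis for 8 genes that passed the threshold with both pairings, by diet; points are the 4 sufficient (blue) and 8 deficient (orange) arrays, squares male and circles female, and lines are diet means. Every deficient array of C1qtnf3, Mfap4, Tppp and Per2 lies above the sufficient arrays, and every deficient array of Cxcl1, Mzb1, Socs3 and Dusp1 below them.

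The remaining genes past the threshold with sex-matched pairs, chosen after their values were seen, were mostly lower. Irf4, a transcription factor of plasma cells, fell by 1.38 (-1.24 with signals raised to the detection floor) and was detected on 2 of 8 deficient arrays. Prg2, the major basic protein of eosinophils, was at least 2.07-fold lower (adjusted p = 0.000573 and 0.0218) and Ccl4, a chemokine of macrophages and T cells, at least 2.74-fold lower (adjusted p = 0.000244 and 0.0250), both not well above background on any deficient array. Serpina3n, a protease inhibitor of the acute phase, fell by 1.90, and Krt23, a keratin, fell by 1.72. Ckmt2, a mitochondrial creatine kinase, fell by 1.35 (SE 0.08 and 0.10), with the smallest p of any probe in that fit, and was detected on 7 of 8 deficient arrays. Fos, Zfp36, Egr2, Dusp1, Egln3, Timp1, Vmp1, Marcksl1, Ceacam10, Kyat1, Lrmp and Ankrd22 also fell; Egr2, Marcksl1 and Vmp1 were detected on 2, 5 and 7 of 8 deficient arrays. Dusp26 rose by 1.17, Leng1 by 1.03, Per2 by 1.05 and Mt1, a metallothionein, by 0.78.

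Of the gene lists, 19 of 43 passed with labelled animals and the preset correlation, 7 higher and 12 lower. With sex-matched pairs 18 of these 19 also passed, in the same direction. Both pairings hold the same arrays and the same log2 differences, so this agreement is not independent support. With an estimated correlation by camera, 0 of 43 passed in either pairing; the lowest adjusted p = 0.126 with an estimated correlation for labelled animals and p = 0.242 for sex-matched pairs, with 5 and 3 lists at unadjusted p under 0.05. fry, which tests a list without comparing it with other genes, passed 18 lists with labelled animals and 1 with sex-matched pairs, the immediate early genes (adjusted p = 0.0248). Of the 19 lists fry did not pass the ATF4 response, the unfolded protein response, the interferon response, goblet cells and smooth muscle.

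Immediate early genes, transcribed within minutes of a stimulus, were lower: of 20 measured, 10 passed lower and 1 higher with labelled animals (12 and 2 adjusted over the list alone), and 6 passed lower with sex-matched pairs (10 lower and 2 higher adjusted over the list alone). Dusp1, a phosphatase that switches off MAP kinases, fell by 1.41 (SE 0.11 and 0.13, adjusted p = 0.000601 and 0.0203), and Egr2, detected on 2 of 8 deficient arrays, by 1.64 (SE 0.12 and 0.22; -1.47 with signals raised to the detection floor). The list mean was -0.71 (adjusted p = 1.65e-06, and p = 0.251 with an estimated correlation). Scores of sex-matched pairs were 0.42 and 0.53 on the sufficient diet and between -0.41 and -0.17 on the deficient diet. Time and handling of tissue collection are not among the sample labels, so their part in these values was not tested.

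Antimicrobial and epithelial inflammation genes were lower, with 12 of 27 past the threshold lower and 1 higher (13 and 1 adjusted over the list alone). With sex-matched pairs 1 passed lower (12 lower and 1 higher adjusted over the list alone). Besides Cxcl1 and Il1b these included Tnf, a cytokine of inflammation, detected on 1 of 8 deficient arrays. Its difference of -1.70 (adjusted p = 0.000381, and 0.0872 with sex-matched pairs) became -1.24 with signals under the detection floor of an array raised to it, so its size is uncertain. The list mean was -0.71 (adjusted p = 1.37e-06, and p = 0.126 with an estimated correlation). Without the sufficient female pair the mean was -0.47 and Tnf stood at -1.12.

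Lists of B and plasma cells, T and NK cells and neutrophils were lower with the preset correlation. Cell numbers were not measured, and a different share of tissue layers in the deficient samples was not tested for these lists. Of 13 B and plasma cell genes, 5 were lower past the threshold (7 adjusted over the list alone; 2 and 5 with sex-matched pairs), with a list mean of -0.71 (adjusted p = 4.45e-05, and p = 0.434 with an estimated correlation). Tnfrsf17, a receptor of plasma cells, was at least 1.71-fold lower with labelled animals (adjusted p = 0.000613, and 0.0855 with sex-matched pairs) and was not well above background on deficient arrays. Of 15 T and NK cell genes 5 were lower (7 lower and 2 higher adjusted over the list alone; 0, and 3 lower, with sex-matched pairs), with a mean of -0.27 (adjusted p = 0.00275, and p = 0.251 with an estimated correlation). Ctla4, an inhibitory receptor of T cells, was at least 2.08-fold lower with labelled animals (adjusted p = 0.000343, and 0.0830 with sex-matched pairs) and Cd3g, a chain of the T cell receptor complex, stood at -0.71 ± 0.08 (SE). Of 7 neutrophil genes 3 were lower (4 adjusted over the list alone; 0 and 4 with sex-matched pairs), with a mean of -0.96 (adjusted p = 0.0104, and p = 0.434 with an estimated correlation); Fpr2, a receptor for bacterial peptides, stood at -1.02 ± 0.10 and S100a9 at -1.73 ± 0.44, detected on 6 and 2 of 8 deficient arrays. With signals raised to the detection floor these were -0.94 and -1.39. The SEs of Fpr2 and S100a9 with sex-matched pairs were 0.32 and 0.48. Without the sufficient female pair the neutrophil mean was -0.65 (adjusted p = 0.136) and Fpr2 stood at -0.49; without the sufficient male pair Fpr2 stood at -1.54. The 21 macrophage and dendritic cell genes did not pass as a list (mean -0.10, adjusted p = 0.316). Their mean was -0.04 without deficient 1, -0.06 without deficient 2 and -0.15 (adjusted p = 0.0732) without the rejoined deficient male pair. The 3 erythrocyte genes measured, too few for a list test, were lower too, with a mean of -1.07, 2 past the threshold and 3 adjusted over the list alone (0 and 3 with sex-matched pairs). Their scores were 1.26 and 0.17 in the sufficient male and female pairs and -0.67 to 0.19 in the deficient pairs.

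Lists of fibroblasts and matrix, enteric neurons and glia, and smooth muscle were higher with the preset correlation. Of 30 fibroblast and matrix genes, 15 were higher and 1 lower past the threshold (22 and 2 adjusted over the list alone; 1 higher, and 8 higher and 1 lower, with sex-matched pairs). The list mean was 0.57 (adjusted p = 5.91e-09, and p = 0.367 with an estimated correlation). Of 18 genes of enteric neurons and glia, 9 were higher (15 adjusted over the list alone; 0 and 8 with sex-matched pairs), among them Stmn2 and Sncg, neuronal cytoskeletal and synaptic proteins, at 1.08 ± 0.14 and 0.94 ± 0.14 (SE), and Syt1, a synaptic vesicle calcium sensor, at 0.67 ± 0.09. Their list mean was 0.63 (adjusted p = 1.35e-08, and p = 0.312 with an estimated correlation). Smooth muscle genes had a mean of 0.31 (2 of 21 higher, 3 adjusted over the list alone, 0 with sex-matched pairs; adjusted p = 0.00671, and p = 0.640 with an estimated correlation), with Pln, a regulator of the muscle calcium pump, at 1.01 ± 0.23 (detected on 1 of 4 sufficient arrays) and Synm at 0.85 ± 0.20. The rejoined deficient male pair differed from the other deficient pairs here: its scores were -0.28 for matrix, -0.20 for neurons and -0.43 for smooth muscle, against 0.28 to 0.41, 0.27 to 0.41 and 0.20 to 0.41 in the other 3. The sufficient male and female pairs had scores of -0.20 and -0.56 for matrix, -0.36 and -0.49 for neurons and -0.11 and -0.30 for smooth muscle. The rejoined deficient male pair lay between them for matrix and below both for smooth muscle. Without that pair the smooth muscle mean was 0.49; without deficient 1 it was 0.20 (adjusted p = 0.0531), and without the sufficient female pair it was 0.21 (adjusted p = 0.140). The 18 endothelial genes did not pass as a list (mean 0.07, adjusted p = 0.365). With sex-matched pairs the endothelial mean was 0.16 (adjusted p = 0.0495) without the rejoined deficient male pair and 0.04 (adjusted p = 0.501) without deficient 2.

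Proliferation genes were lower in the mean but this rested on the sufficient female pair. Of 38 cell cycle genes 10 were lower (17 adjusted over the list alone; 0 with sex-matched pairs either way), among them Tk1, thymidine kinase, at -0.93 ± 0.11 (SE), and Cdk1, the mitotic kinase, at -0.75 ± 0.14. With sex-matched pairs their SEs were 0.29 and 0.45 (adjusted p = 0.223 and 0.469). The list mean was -0.37 (adjusted p = 1.65e-06, and p = 0.126 with an estimated correlation). Scores were 0.64 in the sufficient female pair, -0.15 in the sufficient male pair and between -0.23 and -0.04 in the deficient pairs. Without the sufficient female pair the mean was 0.03 (adjusted p = 0.689), and without the sufficient male pair it was -0.76; Cdk1 then stood at 0.21 and -1.70, and Tk1 at -0.35 and -1.50.

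Of the metabolic and stress lists, 5 were lower with the preset correlation: cholesterol synthesis, fatty acid oxidation, hypoxia, the ATF4 response and the unfolded protein response. Of 18 cholesterol synthesis genes 8 were lower (15 adjusted over the list alone; 0 and 7 with sex-matched pairs), with Cyp51, which demethylates lanosterol, at -0.69 ± 0.08 (SE) and Insig1, a sterol sensor of the endoplasmic reticulum, at -0.67 ± 0.10. The SEs of Cyp51 and Insig1 with sex-matched pairs were 0.17 and 0.20. The list mean was -0.43 (adjusted p = 8.10e-08, and p = 0.312 with an estimated correlation). Fatty acid oxidation and PPAR targets had a mean of -0.29 (3 of 25 lower, 5 adjusted over the list alone, 0 and 3 with sex-matched pairs; adjusted p = 0.00165, and p = 0.312 with an estimated correlation), with Angptl4, a lipase inhibitor, at -1.01 ± 0.15. Hypoxia and glycolysis genes had a mean of -0.27 (5 of 25 lower, 10 adjusted over the list alone, 1 and 2 with sex-matched pairs; adjusted p = 9.20e-05, and p = 0.398 with an estimated correlation), and Egln3, an oxygen-sensing prolyl hydroxylase, fell by 1.34 (SE 0.15 and 0.17). The amino acid response list of ATF4 had a mean of -0.23 (5 of 32 lower, 5 adjusted over the list alone, 0 and 1 with sex-matched pairs; adjusted p = 0.000656, and p = 0.434 with an estimated correlation), with Nupr1, a stress-induced nuclear protein, at -0.72 ± 0.09. The unfolded protein response had a mean of -0.24 (4 of 24 lower, 4 adjusted over the list alone, 0 and 2 with sex-matched pairs; adjusted p = 0.000981, and p = 0.434 with an estimated correlation), with Calr, the chaperone calreticulin, at -0.71 ± 0.12 and Edem1, detected on 4 of 8 deficient arrays, at -0.89 ± 0.10. Without the sufficient female pair Insig1 stood at -0.33 and the fatty acid oxidation mean was -0.20 (adjusted p = 0.0623). Without the sufficient male pair Insig1 stood at -1.02 and the unfolded protein response mean was -0.17 (adjusted p = 0.0580). Fatty acid synthesis (mean -0.20, adjusted p = 0.0812), oxidative phosphorylation (-0.05, 0.166), xenobiotic phase I (-0.09, 0.344) and NRF2 and glutathione (-0.04, 0.323) did not pass, nor did heat shock genes (mean 0.22, adjusted p = 0.115). With sex-matched pairs, fatty acid synthesis had a mean of -0.36 (adjusted p = 0.00371) without the sufficient male pair, -0.24 (adjusted p = 0.0306) without deficient 2 and -0.04 (adjusted p = 0.986) without the sufficient female pair. Oxidative phosphorylation had a mean of -0.11 (adjusted p = 0.00532) without the sufficient female pair, -0.07 (adjusted p = 0.0437) without deficient 2 and 0.02 (adjusted p = 0.899) without the sufficient male pair. The heat shock mean was 0.32 (adjusted p = 0.00187) without the deficient female pair and 0.12 (adjusted p = 0.465) without deficient 2. Without the sufficient female pair the means of xenobiotic phase I and of NRF2 and glutathione were both 0.05. Without the sufficient male pair they were -0.24 and -0.14.

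Of the epithelial lists, goblet cell genes were lower with labelled animals (4 of 17 lower, 5 adjusted over the list alone, 0 with sex-matched pairs either way). The mean was -0.29 (adjusted p = 0.0270, p = 0.486 with an estimated correlation and p = 0.120 with sex-matched pairs), and it was -0.05 without the sufficient male pair, -0.53 (adjusted p = 0.000173) without the sufficient female pair and -0.45 (adjusted p = 0.00247) without the rejoined deficient male pair. With labelled animals it was -0.23 (adjusted p = 0.136) without deficient 1. Spink4, a goblet cell peptide, stood at -0.84 ± 0.15 (SE), at -0.16 without the sufficient male pair and at -1.52 without the sufficient female pair. Epithelium in general had a mean of -0.18 (adjusted p = 0.0646, and 0.0472 with sex-matched pairs), and with sex-matched pairs it passed without deficient 2 (adjusted p = 0.0438) and without the rejoined deficient male pair (adjusted p = 0.0135), while without each of the other 4 the adjusted p was 0.0710 to 0.193. Absorptive colonocytes (mean -0.16, adjusted p = 0.336), enteroendocrine cells (-0.10, 0.486) and tuft cells (-0.03, 0.635) did not pass; 3 of 25 colonocyte genes were higher and 3 lower, and 2 of 17 enteroendocrine genes lower. Without the sufficient male and female pairs the means were -0.34 (adjusted p = 0.0799) and 0.03 for colonocytes, -0.04 and -0.15 for enteroendocrine cells and 0.12 and -0.19 for tuft cells. In the colonocyte list the median was 0.01, against the negative mean, and in the enteroendocrine list also 0.01.

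Anterior Hox genes, which mark more proximal segments, had a mean of 0.35 (5 of 10 higher, 5 adjusted over the list alone, 0 and 5 with sex-matched pairs; adjusted p = 0.0168, and p = 0.312 with an estimated correlation), with Hoxb5 at 0.81 ± 0.13 (SE) and Hoxa5 at 0.65 ± 0.13; Hoxa5 stood at 0.42 without the sufficient female pair. The Hox mean was 0.31 to 0.40 with each sex-matched pair left out (adjusted p = 0.00297 to 0.0275). Distal colon positional genes had a mean of -0.18 (adjusted p = 0.315); the score of the rejoined deficient male pair was -0.67, those of the other deficient pairs -0.09 to 0.34, and without it the mean was 0.02. Small intestine and Paneth cell genes had a mean of 0.52 (1 of 18 higher, 4 adjusted over the list alone, 0 and 1 with sex-matched pairs; adjusted p = 0.0215, and p = 0.312 with an estimated correlation), 0.25 (adjusted p = 0.284) without the sufficient male pair, 0.79 without the sufficient female pair and 0.49 (adjusted p = 0.0732) without the rejoined deficient male pair. Circadian clock genes were higher in the mean at 0.20 (6 of 15 higher and 2 lower, 7 and 2 adjusted over the list alone, 1 higher, and 5 and 2, with sex-matched pairs; adjusted p = 0.0214, and p = 0.434 with an estimated correlation). Per2, a repressor of the clock, rose by 1.05 (SE 0.08 and 0.12, adjusted p = 0.000885 and 0.0250), while Arntl, its activator, stood at -0.80 ± 0.10 and Nfil3 at -1.47 ± 0.17 (SE). The clock mean was 0.16 (adjusted p = 0.0810) without the sufficient female pair, 0.17 (adjusted p = 0.0502) without deficient 1 and 0.15 (adjusted p = 0.0747) without the deficient female pair. Arntl stood at -1.23 without the sufficient male pair and -0.37 without the sufficient female pair, where Nfil3 stood at -0.88. The hour of collection is not among the sample labels, so its part in the clock values was not tested.

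Interferon response genes had a mean of 0.59 (3 of 35 higher, 2 adjusted over the list alone, 0 with sex-matched pairs either way; adjusted p = 1.06e-05, and p = 0.570 with an estimated correlation). The list mean rested on the rejoined deficient male pair, whose score was 1.55. The other 3 deficient pairs lay between -0.30 and -0.21 and the sufficient pairs at -0.29 and -0.49. Without that pair the mean was 0.13 (adjusted p = 0.103). The 3 genes past the threshold, Ifi27, Tap2 and Irgm1, stood at 0.51 ± 0.09, 0.70 ± 0.15 and 0.42 ± 0.11 (SE). They rested less on the rejoined deficient male pair, and without it stood at 0.49, 0.52 and 0.36. Without the sufficient female pair they stood at 0.20, 0.46 and 0.52. Genes of MHC class II and antigen presentation had a mean of 0.26 (adjusted p = 0.486) and a score of 0.93 in the same pair; without that pair the mean was -0.02.

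Lists of methyl group metabolism and its targets did not pass by camera. The means were 0.00 for 21 folate cycle genes (adjusted p = 0.486), -0.02 for 23 genes of the methionine cycle and transsulfuration (0.704), -0.06 for 16 genes of choline, betaine and phospholipid methylation (0.316), -0.02 for 19 genes of DNA methylation and demethylation (0.825), 0.03 for 39 genes of histone methylation (0.729) and 0.05 for 24 imprinted genes (0.405). Without the sufficient male and female pairs these means were -0.02 and 0.03 for folate, -0.06 and 0.01 for methionine, and -0.10 and -0.02 for choline. They were -0.05 and 0.01 for DNA methylation, 0.05 and 0.00 for histone methylation, and 0.04 and 0.06 for imprinted genes. The folate list median was -0.03 and its test pointed down, against the mean. The histone methylation median was -0.01, also against its mean. By fry, the choline list passed lower (adjusted p = 0.0266) and the imprinted genes higher (adjusted p = 0.0397) with labelled animals, and neither with sex-matched pairs (0.113 and 0.483). Past the threshold were 1 folate gene higher and 1 lower, 2 lower in the methionine list, 2 higher and 2 lower in the choline list, 2 lower in DNA methylation and 0 in histone methylation. Of the imprinted genes 3 were higher and 1 lower. Adjusted over the list alone, 4 imprinted genes were higher and the other counts were the same. With sex-matched pairs 0 passed in each of these lists, and adjusted over the list alone 1 methionine gene passed lower. Ahcy, which hydrolyses S-adenosylhomocysteine, stood at -0.58 ± 0.11 (SE, adjusted p = 0.0160 with labelled animals and 0.0927 with sex-matched pairs). The DNA methyltransferase genes Dnmt1 and Dnmt3b stood at -0.05 ± 0.17 and 0.20 ± 0.10 (adjusted p = 0.885 and 0.208 with labelled animals). Over the alternatives of processing and replicates Dnmt1 ran from -0.15 to 0.06.

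Wnt targets and crypt base stem cell genes did not pass as a list by camera (mean 0.05, 3 of 28 higher and 3 lower, 5 and 4 adjusted over the list alone, 0, and 1 lower, with sex-matched pairs; adjusted p = 0.316). By fry the list passed higher with labelled animals (adjusted p = 0.0407) and did not with sex-matched pairs (adjusted p = 0.466). The mean was 0.19 without the sufficient male pair and -0.09 without the sufficient female pair. Lgr5, a receptor of crypt base stem cells, stood at -1.16 ± 0.14 (SE, adjusted p = 0.00432 with labelled animals and 0.0540 with sex-matched pairs) and was detected on 4 of 8 deficient arrays. Axin2, a feedback target of Wnt signalling, stood at 0.12 ± 0.17 (adjusted p = 0.667; 0.30 without the sufficient male pair and -0.05 without the sufficient female pair), Myc, detected on 3 of 8 deficient arrays, at -0.45 ± 0.12 (adjusted p = 0.0510, and 0.267 with sex-matched pairs; -0.28 without the sufficient female pair), and Apc at 0.08 ± 0.12 (adjusted p = 0.723). Apc stood at 0.03 without the sufficient male pair and at 0.13 without the sufficient female pair. Targets of p53 (mean -0.18, adjusted p = 0.160) and base excision and mismatch repair genes (0.02, 0.627) did not pass by camera. By fry the p53 list passed lower with labelled animals (adjusted p = 0.0288) and did not with sex-matched pairs (adjusted p = 0.124). Of 26 p53 targets 4 were lower (6 adjusted over the list alone; 0 and 2 with sex-matched pairs), and 0 of 22 repair genes passed. The repair mean was -0.03 without deficient 2 and 0.08 without the deficient female pair. Cdkn1a, a cell cycle inhibitor induced by p53, stood at -0.79 ± 0.14 (adjusted p = 0.0135 and 0.138).

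Among markers of other tissues, 10 adipocyte genes (mean -0.44, adjusted p = 0.160) and 5 pancreas genes (-0.33, 0.866) did not pass. The pancreas mean was 0.41 without the sufficient male pair and -1.07 without the sufficient female pair. With sex-matched pairs the adipocyte mean was -0.69 (adjusted p = 0.00107) without deficient 2 and -0.23 (adjusted p = 0.253) without deficient 1. The pancreas score was 0.96 in the sufficient male pair and 0.87 in deficient 2, the pairs with high Tgm4, and between -0.54 and -0.31 in the other 4. Lists with fewer than 5 measured genes were not tested: mast cells (4 genes, mean -0.39), erythrocytes (3 genes, mean -1.07), interstitial cells of Cajal (1 gene, Ano1, -0.26) and sex chromosome genes (4 genes, mean 0.44).

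**Figure D3:**
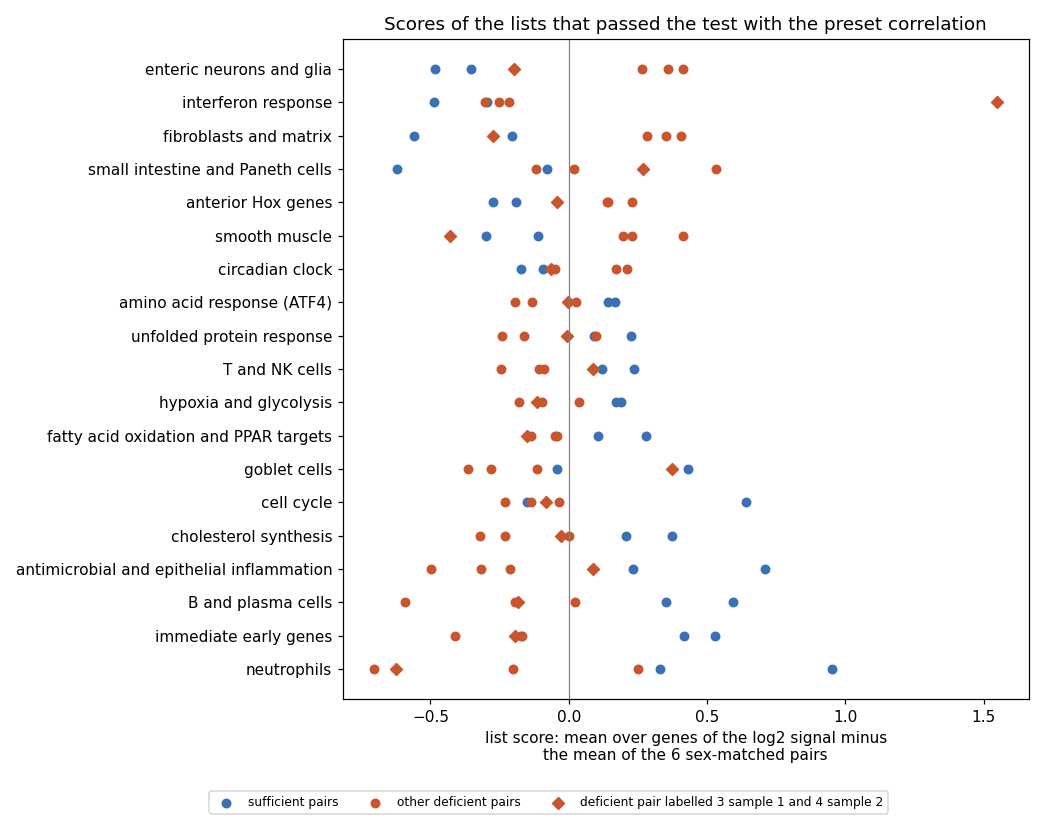
Scores of the 19 lists past the threshold with labelled animals and the preset correlation; the horizontal axis is the mean log2 signal of the list's genes minus the mean of the 6 sex-matched pairs, and points are pairs (blue sufficient, orange deficient, diamonds the rejoined deficient male pair). The interferon score of that pair is 1.55 and the other 5 pairs lie below 0.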

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

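The search for values that stand apart was planned for the labelled animals; its use on sex-matched pairs and the tests of both patterns were chosen after the result was seen.

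Values that stand apart among the 4 deficient animals were searched over 79 named genes and 43 lists with labelled animals and 43 lists with sex-matched pairs. Of these 165 values in all, 15 passed Dixon's critical value for 4 values. Chance alone passes about 1 in 20 for independent values, and values of overlapping genes and pairings are not independent. The other 2 labelled deficient animals than 1 and 2 each average an array of the rejoined male pair and an array of the deficient female pair. This draws their means together, so the rate does not hold with labelled animals. Labelled deficient animal 2 stood above the other 3 in Pdzk1 (8.0, the next at 7.18), Mzb1 (6.90, next 5.78), Creb3l3 (6.49, next 5.08), S100a9 (6.42, next 4.95) and Apoa1 (11.79, next 10.69), and below them in Hoxa5 (9.70, next 10.06). It also stood above them in the scores of imprinted genes (0.054), of small intestine and Paneth cells (0.53) and of pancreas (0.87 with either pairing). Labelled deficient animal 1 stood above the others in C1qtnf3 (9.35, next 8.74) and Il17d (7.53, next 7.10). With sex-matched pairs only, it passed as below the others in the score of immediate early genes (-0.41, next -0.20). The rejoined deficient male pair stood above the others in the interferon score (1.55, next -0.21) and below them in the endothelium score (-0.23, next 0.10).

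The first pattern weighed is the opposite sex of samples with the same animal label. RNA of both sexes in a tube would put Xist and a Y-linked gene on the same array, and 0 of 12 arrays detected both. Sample labels exchanged between animals of the same diet may be the source: among all 315 ways to pair the arrays within the diets, the sex-matched pairing had rank 1 by mean correlation over autosomal probes (0.518), narrowly above the next (0.512), and the labelled pairing ranked 179 (0.0850). An exchange between diets, or an additional mouse, was not tested, and no biological explanation was tested.

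The second pattern is the count of 1460 probes with labelled animals against 38 with sex-matched pairs. Averaging arrays of different mice may hide the spread between mice. The median SD between the means was 0.740 times as large with labelled pairs as with sex-matched pairs. Both pairings divide the same arrays within a diet. This ratio therefore restates the larger SD within labelled pairs and is no separate test. In simulated sets with no diet effect that averaging raised the share of probes at unadjusted p under 0.05 to 7.89%, against 28.7% observed, yet it called at most 2 probes; simulated probes were independent, so how much of the count the averaging gives stays open. Of 15 splits of the labelled animals into 2 and 4, 1, the real split, gave 1460 probes and the highest other gave 72; with sex-matched pairs 1 gave 38 and the highest other 17. With 15 splits the share cannot fall under 0.05.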

How the results depend on the processing

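The alternatives that join arrays by sex, and those built on them, were chosen after seeing the data. The labelled count of 1460 probes stayed within 1.5 times under the 5 other background corrections, normalizations and sources of values, both filters, 12 arrays as independent or with the labelled animal as a random block, and a variance trend. It moved to 35 and 28 with sample 1 or sample 2 alone, 638 with the animal number as a replicate block, 3518 with array weights, 2594 at adjusted p under 0.10, 3872 at unadjusted p under 0.05, and 87 to 2060 without each labelled animal. It was 38 with arrays paired by sex, 522 and 574 with the sex-matched pair as a random block without and with sex as a covariate, and 98 on the 8 male arrays. Without 1 sufficient animal, the other is assumed to vary like the deficient animals. Animals 1 and 3 of the diets share only a number (correlations of deviations -0.06 and -0.05, 1 residual degree of freedom in that fit). The 5748 probes with no overlap became 854 over 12 arrays in each of the 3 fits of arrays and 6366 to 7774 without each animal, by the number of units compared, and 3249, 3215 and 3379, over as many units, with sample 1 alone, sample 2 alone and arrays paired by sex. The 19 lists became 0 by camera with an estimated correlation in either pairing (5 and 3 at unadjusted p under 0.05) and 1 by fry with arrays paired by sex (12 at unadjusted p under 0.05); they were 19 to 21 without each animal. The count of 38 became 11 with the authors' values, 1 without a filter, 22 with the strict filter, 7 with sex as a covariate, 172 at adjusted p under 0.10, 2023 at unadjusted p under 0.05, 0 to 351 without each pair, and 0 by limma without both pairs with male accessory gland transcripts (1712 at unadjusted p under 0.05; 1 sufficient pair left). The consensus correlation of -0.23 became 0.33 with arrays paired by sex and 0.28 with sex as a covariate. Averaging arrays of different mice was weighed by simulation for 1460 against 38 in the part before this, which left its share of the count open. For the other moves, apart from the fewer units, the cause was not tested. Of 71 named genes past the threshold with labelled animals, 13 passed with arrays paired by sex and 60 with the authors' values, in the same direction. Of the 19 lists, 18 and 19 did. With arrays paired by sex the log2 differences are the same, so their direction was fixed in advance. Probes near background limit what can be seen on deficient arrays for genes that were low there. Slide as a block was not run.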

Other observations

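The test of tissue layer and position below was chosen after the result was seen, as were the genes of the first 2 paragraphs.

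Transcripts known from male accessory glands were high on 4 arrays. Tgm4, the prostate transglutaminase, had log2 signals of 12.51 to 12.83 on both arrays of the sufficient male pair and of labelled deficient animal 2, and 4.57 to 4.73 on the other 8. Pate14 had 10.51 to 11.17 against 4.62 to 4.87, Defb50, a defensin, 8.21 to 10.55 against 4.57 to 5.01, Azgp1 9.16 to 9.94 against 5.67 to 6.62, Rnase1 8.45 to 10.40 against 5.13 to 5.52, and Gsdma 6.80 to 7.37 against 4.61 to 4.93. Msmb, a protein of seminal plasma, had 5.52 to 9.44 against 4.49 to 4.59. These 4 arrays include 1 array from each labelled sufficient animal. Such arrays are found on both diets but not in equal share: without them 1 sufficient pair and 3 deficient pairs were left.

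Interferon-induced genes were high on both arrays of the rejoined deficient male pair. Usp18, which removes the ubiquitin-like ISG15, had 10.31 and 10.48 there, against 5.77 to 6.86 on the other 10 arrays, Oas2, a sensor of double-stranded RNA, 9.25 and 9.42 against 4.93 to 5.99, and Cxcl9, a chemokine induced by interferon gamma, 8.87 and 8.93 against 5.0 to 6.70. Hoxd12, a gene of the posterior body axis, was lower on these arrays, at 5.22 and 5.27 against 6.79 to 7.73, while its neighbour Hoxd13, at 6.33 and 6.56 against 6.43 to 8.25, overlapped them.

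The third pattern weighed is the higher signal of matrix and enteric neuron genes on the deficient diet. More of the muscle and connective layers in the deficient samples may raise them: the smooth muscle score over sex-matched pairs was higher by 0.31 with an SE of 0.28, which leaves this open. A more proximal stretch of colon in the deficient samples may also move them: anterior Hox genes were higher by 0.35 with an SE of 0.09, but the distal positional score differed by -0.18 with an SE of 0.33, which leaves this open as well. Among deficient pairs the rejoined male pair had the lowest Hox score (-0.04, the others 0.14 to 0.23), as it had for matrix, neurons and smooth muscle. The Hox score therefore may not tell position from tissue layer. An effect of the diet on matrix and enteric neuron genes stays open, untested against either explanation. Where along the colon and how deep in the wall the samples were taken is not given in the sources used here.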
